A study of Mus musculus with 12 samples.

How the data were processed

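ATAC-seq peak lists of 12 samples were used, from deep-layer and upper-layer projection neurons of the mouse neocortex at 3 stages each. Per the labels' protocols, the neocortex was dissected from 2 to 8 embryos per replicate, and 250000 to 500000 GFP-positive cells were sorted. Their nuclei were transposed for 30 minutes at 37 degrees, and the libraries were amplified over 12 PCR cycles. The authors deposited 1 list of peak positions per sample, with a chromosome, start, end and name for each peak and no score, height or p-value. Peaks were therefore listed per sample and not for pooled replicates. Per the submitters' processing notes, the tools named were cutadapt, Bowtie2, Picard 1.14.0 and MACS2 2.1.0, and the build was mm9. What each tool did, any shift of reads for the transposase, the peak thresholds and the numbers of reads are not given in the sources used here.

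The build was checked against the positions: peaks on chromosome 1 reached 197184229, and 845 peaks there lay beyond the last gene of a GRCm38 gene table. That table was of another build and was not used for positions. No mm9 annotation or genome sequence was used, so results on genes, gene lists, promoters, motifs and the reporter promoters, which had been planned, are not analysed here, and regions are named by position alone. No peaks overlapped within a list.

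All peaks were merged into consensus regions where they overlapped or touched, and a region was open in a list when at least 1 bp of it was covered by a peak of that list. Similarity of lists was the base-pair Jaccard index (bedtools 2.31.1). Population and stage differences of single values were tested by exact permutation of the list labels. Per region, open lists were compared between populations by Fisher's exact test (scipy 1.17.1), two-sided, with Benjamini-Hochberg adjustment over regions open in 5 to 7 lists, outside which the test cannot give p under 0.05. A region was gained when open in both lists of the last stage and in neither of the first, and lost in the opposite case. With 2 replicates per stage a test per region would have little power, and none was made. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used, and figures were drawn with matplotlib 3.10.9.

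The groups, main tests and most alternative settings were chosen before the data were examined. The rule for named regions took the 3 regions per set with the highest authors' score. Since the lists held no score, the 3 regions with the largest median peak width in the lists that define the set were taken instead, a choice made after seeing the data. Named genes had been fixed too, but none is reported. Added after seeing the data were the counts of completely separated regions, the comparisons among prenatal lists, the reading of 1 population's changing regions in the other, the tests over 1 Mb windows and over chromosomes, 2 further backgrounds for the overlap of changes, these overlaps and the prenatal pairs at equal list length, and alternatives based on peak width and random thinning.

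The number of peaks limits the precision: a weak region can be closed in a list because fewer peaks were called there. Shares of regions in a single list carry 95% Wilson intervals, which cover counting error only. The per-region test was tested on simulated data with the deposited numbers of open lists per region. Over 42767 tested regions it recovered 0% of 200 added regions that separated the populations completely and 100% of 3000, so a small number of separated regions cannot pass after adjustment in a design of 6 against 6. Without adjustment it recovered 100% of both, and 1.03% of unchanged regions had p under 0.05. The simulated open states were spread over the lists by list length alone, without likeness of replicates. The 1.03% need not hold for the real lists. Alternatives were each list left out, 500 bp windows around peak midpoints, no filter on open lists, age-overlapping stages, permutation within replicate number, autosomes only, and the added ones named above.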

Results

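Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 2 populations of projection neurons sorted from the neocortex of CD1 mice. Deep-layer neurons carried the Golli-GFP transgene and were collected at E13.5, E16.5 and E18.5. Upper-layer neurons were marked by in utero electroporation at E15.5 of a plasmid with GFP under a Cdk5r promoter and were collected at E17.5, P1 and P5. Each of the 6 groups had 2 replicates, which gave 12 peak lists, 6 per population. Per the labels, a replicate pooled 2 to 8 embryos. The labels do not say whether the replicates of a group came from separate litters, so p-values measure the spread between these lists, which may be technical. Upper-layer P1 and P5 were the only postnatal groups, so age after birth was not sampled in deep-layer neurons. Positions are on mm9, counted from 1.

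The lists held between 96452 peaks (deep-layer E18.5 replicate 1) and 164508 peaks (upper-layer E17.5 replicate 1), and the number of peaks stands here for depth, since the lists gave no read totals. Deep-layer lists averaged 121705 ± 21347 peaks (SD, n = 6) and upper-layer lists 126925 ± 20095 (SD, n = 6), a difference smaller than the spread between lists (p = 0.658, exact permutation test, two-sided). In deep-layer neurons the median peak width was 393.5 ± 4.95 bp at E13.5 and 446 ± 42.4 bp at E18.5 (SD, n = 2 each). In upper-layer neurons it was 485 ± 5.66 bp at E17.5 and 321 ± 7.07 bp at P5 (SD, n = 2 each). The exact permutation p over the 90 assignments of stage labels was 0.0222 for the deep-layer change, the smallest that a two-sided test allowed here, and 0.133 for the upper-layer change. Merging all peaks gave 498516 consensus regions, of which 265396 were open in a single list and 17048 in all 12. Regions open in 1 list had a median length of 256 bp and regions open in all 12 a median of 1400 bp. Upper-layer P1 and P5 lists held the largest shares of regions found in no other list, between 28.3% and 43.8% per list, against 2.37% to 15.2% in the 8 prenatal lists.

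**Figure D1:**
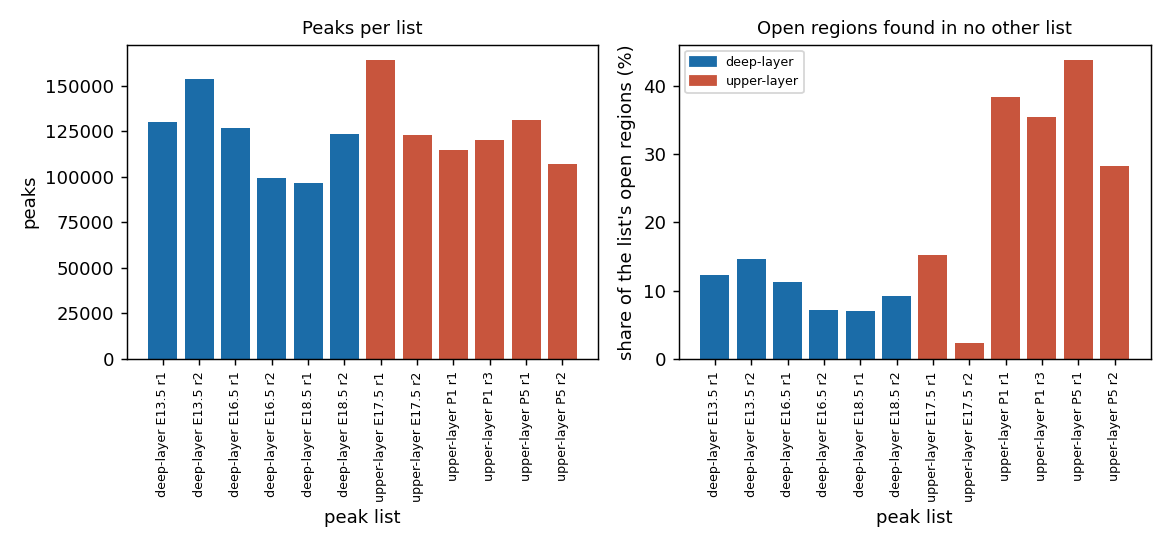
Peaks per list (left, bars start at 0) and the share, in percent, of each list's open consensus regions that were open in no other list (right), for 6 deep-layer lists (blue) and 6 upper-layer lists (red), where r1 to r3 are replicate numbers. The numbers of peaks overlapped between populations, while the 4 P1 and P5 lists had the highest shares of regions of their own, 28.3% to 43.8%.

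Deep-layer lists were more alike across stages than lists of different populations, while upper-layer lists were not. The base-pair Jaccard index, the shared length of 2 lists divided by their joint length, averaged 0.301 between lists of the same population and different stages and 0.244 between populations, a difference of 0.0576 (p = 0.00866, exact permutation of the population label, one-sided). Permuted labels that part replicates count their high index as between populations, which the real labels never do. This p, and those below from the same permutation, therefore partly reflect the likeness of replicates and not population alone. The excess came from deep-layer pairs, whose mean was 0.399, since upper-layer pairs of different stages averaged 0.204, below the mean between populations. Deep-layer E16.5 and E18.5 lists were close to each other, with a mean index of 0.465, and E13.5 stood further from both, at 0.382 and 0.351. Upper-layer E17.5 lists had a higher mean index with deep-layer E13.5 (0.409) than with upper-layer P1 (0.176) or P5 (0.180), and P1 and P5 lists had indices of 0.136 to 0.276 with every prenatal list. Among the 8 prenatal lists alone, a comparison added after the data had been seen, the between-population mean was 0.367, a difference of 0.0326 from the within-population mean of 0.399, which held deep-layer pairs alone because E17.5 was the sole prenatal upper-layer stage. Deep-layer E13.5 was closer to upper-layer E17.5 (0.409) than to the other deep-layer stages (0.382 and 0.351), so stage and population were not separated there. Over all lists, the difference was 0.0270 and 0.0336 without deep-layer E16.5 replicate 1 or 2, 0.0351 without E18.5 replicate 2, and 0.106 and 0.108 without upper-layer E17.5 replicate 1 or 2, with exact permutation p between 0.00433 and 0.0411.

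On average, replicates were more alike than other pairs of the same population, by a Jaccard index of 0.145 (p = 0.00444, exact permutation over all pairings within a population, one-sided). The replicate index was 0.520 at deep-layer E13.5, 0.476 at E16.5 and 0.514 at E18.5. It was 0.641 at upper-layer E17.5, but only 0.272 at P1 and 0.254 at P5. At these 2 stages replicates did not stand apart from lists of different stages: pairs of a P1 and a P5 list averaged 0.256 and reached 0.288, and 2 of them lay at or above each replicate index. For deep-layer E16.5, 1 pair of different stages was higher, at 0.503. The upper-layer E17.5 pair stood apart: 93.4% of the peaks of replicate 2 lay in replicate 1, against at most 80.7% of the shorter list in any other pair, and peak names in both lists carried the same library name. They shared 103 identical intervals, the most of any replicate pair (23 to 46 in the others). Both were kept because the labels list them as separate replicates, and the region counts, stage counts and Jaccard comparisons were repeated without each of them. Without upper-layer E17.5 replicate 1 or 2 the replicate difference was 0.0784 and 0.0841.

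**Figure D2:**
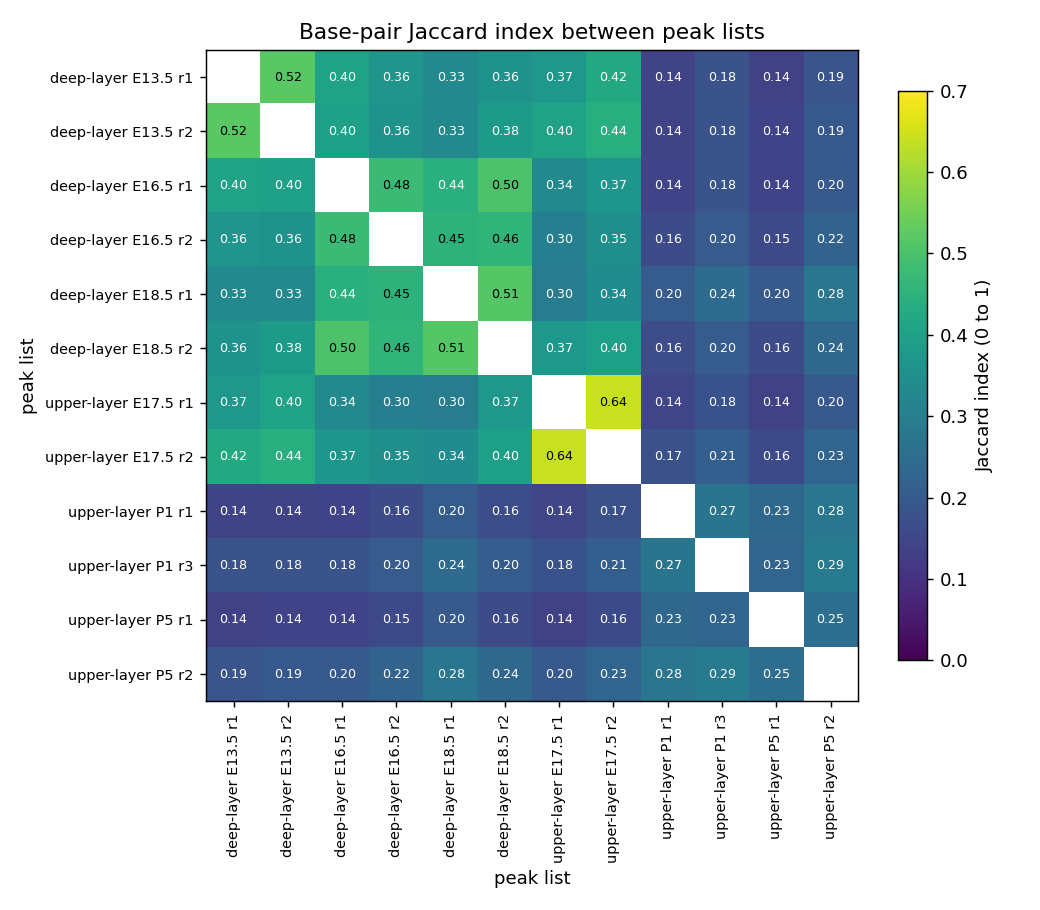
Base-pair Jaccard index (0 to 1, colour and printed value) for every pair of the 12 peak lists, with r1 to r3 as replicate numbers. Deep-layer lists and the upper-layer E17.5 lists form 1 block of higher values, in which the E17.5 replicates reach 0.641, while the P1 and P5 lists stay at or below 0.288 with every list.

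Of the regions that separated the populations completely, 1732 were open in all 6 deep-layer lists and in no upper-layer list, and 117 were open in all 6 upper-layer lists and in no deep-layer list. The P1 and P5 replicates shared little (0.272 and 0.254), which limits how many regions can be open in all 6 upper-layer lists. Random labels would give 14.7 such regions per side from the 13620 regions open in exactly 6 lists. The deep-layer regions with the widest peaks lay on chromosome 10 from 24708662 to 24710937 (median peak width 1704.5 bp), on chromosome 10 from 28531537 to 28533348 (1351 bp) and on chromosome 18 from 86507750 to 86509465 (1317.5 bp). The corresponding upper-layer regions lay on chromosome 11 from 96999266 to 97000736 (756.5 bp), on chromosome 5 from 130267207 to 130268516 (720 bp) and on chromosome 5 from 118558181 to 118559141 (645 bp). These counts were added after the data had been seen, and an exact permutation test over all splits of the lists into 6 and 6 gave p = 0.00433 for their sum of 1849, which 1 other split exceeded with 2074. Most of these splits part replicates, which lowers their counts, so this p does not measure population alone. Splits of other sizes, such as by birth, were not among them. Beside the population counts, 8936 regions were open in all 8 prenatal lists and in no postnatal list. Another 2737 were open in all 4 postnatal lists and in no prenatal list. The population counts fell to 937 and 38 after random thinning to equal list length and to 1019 and 62 when 0.5 of the region had to be covered. They were 2130 and 86 with an equal number of the widest peaks. The deep-layer count was 2647 without upper-layer E17.5 replicate 1. The upper-layer count was 176 without deep-layer E13.5 replicate 2, 185 without upper-layer E17.5 replicate 2, 184 and 205 without P1 replicate 1 or 3 and 209 without P5 replicate 1.

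The test fixed for this comparison was Fisher's exact test per region, two-sided, with Benjamini-Hochberg adjustment over the 42767 regions open in 5 to 7 lists. No region passed an adjusted p of 0.05 in either direction, while 5262 regions had an unadjusted p under 0.05 with more open deep-layer lists and 701 with more open upper-layer lists. The smallest p that 6 lists against 6 allow, 0.00216, was reached by 1849 regions with an adjusted p of 0.0501, where 1852 such regions would have been needed to pass. The count therefore turned on small changes: with autosomes only, 1668 deep-layer and 112 upper-layer regions passed, and with an equal number of the widest peaks per list 2130 and 86 passed. After random thinning to equal length none passed by Fisher's exact test (smallest adjusted p 0.0939, with 5138 and 331 regions at an unadjusted p under 0.05). With age-overlapping stages only (deep-layer E16.5 and E18.5 against upper-layer E17.5 and P1), none passed, at a smallest adjusted p of 0.0805 by Fisher's exact test, with 6538 and 747 regions at an unadjusted p under 0.05.

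The 8 prenatal lists were compared alone, a comparison added after the data had been seen. Both upper-layer E17.5 lists were open in 16218 regions in which all 6 deep-layer lists were closed, against 7550, 753 and 2734 regions open only in the replicate pairs of deep-layer E13.5, E16.5 and E18.5. With 4 replicate pairs the smallest possible exact permutation p is 0.25, so no test is given, and the E17.5 lists, which overlapped more than any other pair, may not be independent. The E17.5 lists were also the longest on average: at equal list length the count was 10651 with the widest peaks (5314, 1163 and 3248 for the deep-layer pairs) and 9320 after thinning (4842, 1059 and 3069). The widest of these regions lay on chromosome 5 from 126137613 to 126140047 (median peak width 1901.5 bp), on chromosome 14 from 103027583 to 103029363 (1709 bp) and on chromosome 8 from 94497262 to 94499037 (1591 bp). Few of the 16218 regions were open in later upper-layer lists, 6.29% to 9.57% per P1 or P5 list and 7.34% on average, against 59.6% of the regions open in all prenatal lists. The 2 sets were not matched on width: the median peak width was 477 bp in the former and 1037 bp in the latter. Regions open only in the deep-layer E13.5, E16.5 or E18.5 pair averaged 3.47%, 4.08% and 11.7% in P1 and P5 lists. The 7.34% lay within that range. In the other direction, 2446 regions were open in all 6 deep-layer lists and in neither upper-layer E17.5 list, of which 12.9% on average were open in P1 and P5 lists, led by a region on chromosome 6 from 36216604 to 36218986 (1820.5 bp). The corresponding counts were 1577, 683 and 1678 for the deep-layer replicate pairs of E13.5, E16.5 and E18.5, and 1 pair of different stages reached 2651. Of the regions of these replicate pairs, 29.9%, 39.2% and 11.8% on average were open in P1 and P5 lists. Without upper-layer E17.5 replicate 2 the 16218 regions became 43578, and without replicate 1 the 2446 regions became 3932, since a single list then defined the stage.

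Deep-layer neurons both lost and gained open regions between E13.5 and E18.5, and which count was larger depended on list length and on the replicates. In the full lists, 28154 regions were open in both E13.5 lists and in neither E18.5 list, and 13979 showed the opposite, a ratio of 2.01, but the E13.5 lists were longer (141942 ± 16900 peaks against 110146 ± 19366 at E18.5, SD, n = 2 each). With an equal number of the widest peaks per list, 18498 were lost and 16944 gained, and with lists thinned at random to equal length 14803 were lost and 16554 gained. In the full lists 49919 regions were open at both stages. The E16.5 lists were open in 58.8% ± 10.6 (SD, n = 2) of the gained regions and in 21.2% ± 11.6 (SD, n = 2) of the lost ones, and 6135 of the gained and 2257 of the lost regions were open in both E16.5 lists. The widest gained regions lay on chromosome 8 from 50292710 to 50294866 (median peak width 1795 bp at E18.5), on chromosome 9 from 17097813 to 17099608 (1756 bp) and on chromosome 4 from 7522465 to 7524318 (1711 bp). All 3 were open in 4 deep-layer lists. The widest lost regions lay on chromosome 14 from 115480116 to 115481740 (1508 bp at E13.5), on chromosome 19 from 14500339 to 14502165 (1451 bp) and on chromosome 5 from 41673335 to 41674922 (1440.5 bp). Over the 90 assignments of stage labels, the lost count had p = 0.0222 and the gained count p = 0.1 (exact permutation, one-sided, smallest possible 0.0111). The p of the lost count was 0.0667 without E13.5 replicate 1 or 2, E16.5 replicate 1 or E18.5 replicate 1, and 0.0333 without E16.5 or E18.5 replicate 2 (exact permutation). At equal length the gained count had p = 0.0333 with the widest peaks and p = 0.0111 after thinning (exact permutation). With a single list for a stage the counts rose: to 64235 and 51057 lost regions without E13.5 replicate 1 or 2, and to 37580 and 27548 gained regions without E18.5 replicate 1 or 2. Without E18.5 replicate 1 the gained regions outnumbered the lost ones, 37580 against 29688. Without E18.5 replicate 2 they did not, at 27548 against 42224.

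Upper-layer neurons lost 66156 regions between E17.5 and P5 and gained 14822, a ratio of 4.46, and 26913 regions were open at both stages. The E17.5 lists were longer than the P5 lists on average (143868 ± 29189 peaks against 119310 ± 17010, SD, n = 2 each), and lost regions also outnumbered gained ones with an equal number of the widest peaks (43063 and 12934) and after thinning (32306 and 12150). The excess of losses depended on the replicates: without P5 replicate 1 there were 71542 lost and 56954 gained regions, and without P5 replicate 2 gained regions outnumbered lost ones, 88565 against 78638. A gained region then needed the remaining P5 list alone, while a lost one still needed both E17.5 lists. P5 replicates 1 and 2 held 54762 and 28566 regions open in no other list, which then counted as gained. Asking both lists of a stage to be open favours losses here, since the E17.5 lists had a Jaccard index of 0.641 and the P5 lists 0.254. The losses were already present at P1, where the lists were open in only 8.63% ± 4.06 (SD, n = 2) of the lost regions, while the gained regions were open in 49.6% ± 2.27 (SD, n = 2). The widest gained regions lay on chromosome 15 from 75933130 to 75936302 (median peak width 2986 bp at P5), on chromosome 7 from 48427869 to 48430815 (2728.5 bp) and on chromosome 2 from 80654285 to 80657196 (2690 bp). All 3 were also open in 2 or 3 deep-layer lists. The widest lost regions lay on chromosome 13 from 98178318 to 98181139 (2795.5 bp at E17.5), on chromosome 4 from 35641523 to 35643971 (2377.5 bp) and on chromosome 19 from 15910825 to 15913586 (2355 bp), and were open in 4, 6 and 5 deep-layer lists. The lost count had p = 0.0444 and the gained count p = 0.111 over 90 assignments (exact permutation, one-sided), so the gained count was within what other orders of the stages gave. The p of the lost count was 0.233 and 0.133 without E17.5 replicate 1 or 2, 0.1 without P1 replicate 3 or P5 replicate 1, 0.0667 without P5 replicate 2 and 0.0333 without P1 replicate 1 (exact permutation). Without E17.5 replicate 2 the lost count rose to 110079.

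Many regions counted as lost in deep-layer neurons were also counted as lost in upper-layer neurons. Of the regions lost in deep-layer neurons, 11951 were also lost in upper-layer neurons, where independent sets among all consensus regions would share 3736, a ratio of 3.20. With 2 backgrounds added after the data had been seen, regions open in 2 or more lists and regions open in 2 or more lists of each population, the ratio was 1.496 and 1.73. The count itself depended on list length, with 7047 regions for an equal number of the widest peaks and 3110 after thinning, while the ratio stayed above 1 with every background (3.25, 1.58 and 1.96 with the widest peaks, 2.85, 1.27 and 2.297 after thinning). For the 702 regions gained in both the direction turned with the background, at ratios of 1.69, 0.790 and 6.48, so no excess is claimed. Opposite changes were rarer than for independent sets with each background in the full lists, but after thinning the regions gained in deep-layer and lost in upper-layer neurons had a ratio of 1.142 with all regions. In the full lists and with all regions, 1508 regions were gained in deep-layer and lost in upper-layer neurons (ratio 0.813), and 92 were lost in deep-layer and gained in upper-layer neurons (ratio 0.110). Among the 14253 regions that changed in both, 88.8% changed in the same direction, where independent directions would give 80.7%, and the odds ratio was 60.5. The comparisons shared no lists, but regions are not independent replicates, so no p is attached. A region lost in both must first be open at E13.5 and E17.5, whose lists were alike (mean Jaccard index 0.409). No background was limited to such regions, so these ratios do not separate shared closing from shared openness at the first stages. Regions open at both deep-layer end stages also fell in upper-layer lists, from 91.2% at E17.5 to 53.5% at P5. The gained overlap rose to 1061 and 2828 without deep-layer E18.5 replicate 1 or 2 and to 1460 and 1119 without upper-layer P5 replicate 1 or 2, and the lost overlap rose to 19674 without E18.5 replicate 2.

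Read in upper-layer lists, the regions that deep-layer neurons lost were far more often open at E17.5 than after birth. This comparison was added after the data had been seen. Of the deep-layer lost regions, 56.8% ± 6.01 were open in upper-layer lists at E17.5, 6.42% ± 0.972 at P1 and 5.86% ± 0.168 at P5 (SD, n = 2 each). Of the deep-layer gained regions, 27.3% ± 7.24 were open at E17.5, 12.9% ± 3.02 at P1 and 19.6% ± 4.09 at P5 (SD, n = 2 each), so their mean level was lower at P5 than at E17.5. Gained regions made up 19.1% ± 2.50 of the open regions of both sets at E17.5, 49.8% ± 2.1 at P1 and 62.1% ± 5.60 at P5 (SD, n = 2 each). The difference of 43.0 percentage points between P5 and E17.5 had p = 0.0222 (exact permutation over 90 assignments, two-sided, the smallest possible). For a single list the 95% Wilson interval was narrow, such as 20.3% to 21.4% for E17.5 replicate 1, and these intervals cover counting error only.

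In the reverse reading, regions gained in upper-layer neurons made up 2.40% ± 0.684 of the upper-layer changing regions open in deep-layer lists at E13.5, 4.69% ± 1.56 at E16.5 and 10.96% ± 7.37 at E18.5 (SD, n = 2 each). The difference of 8.56 percentage points between E18.5 and E13.5 had p = 0.0444 (exact permutation over 90 assignments, two-sided). It rested mostly on deep-layer E18.5 replicate 1, at 16.2%, and without that list it was 3.35 (p = 0.1, exact permutation), while without E18.5 replicate 2 it was 13.8 (p = 0.0333, exact permutation). Without E13.5 replicate 1 or 2 the p was 0.267, and without E16.5 replicate 1 or 2 it was 0.133 and 0.0667 (exact permutation).

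**Figure D3:**
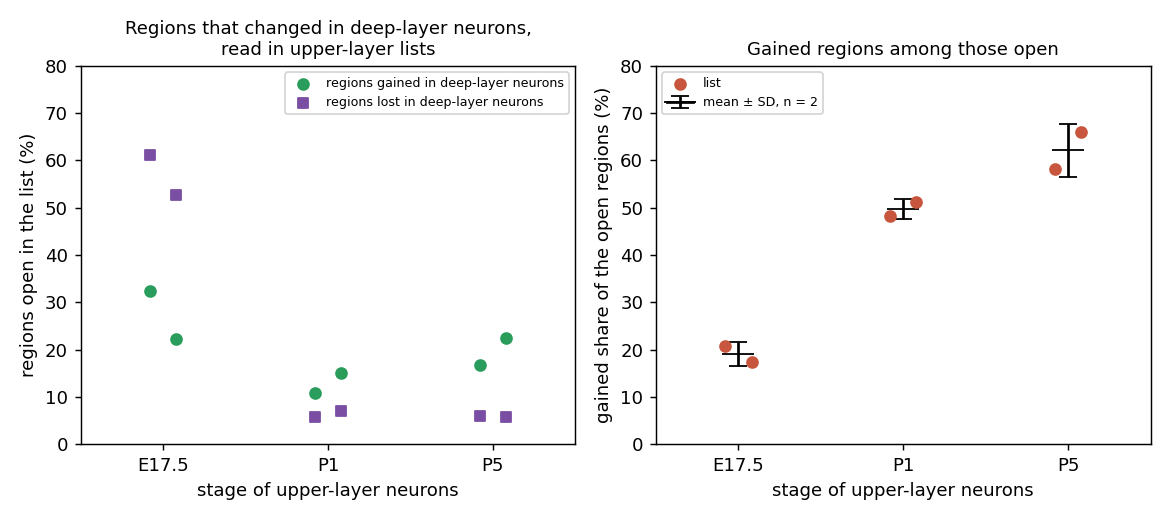
Left, the share in percent of the 13979 regions gained (circles) and the 28154 regions lost (squares) by deep-layer neurons that was open in each upper-layer list, by stage. Right, the gained regions as a percent of those of both sets that were open in each list, with each list as a point and the mean ± SD (n = 2) as bars: both lists lie near 19.1% at E17.5 and near 62.1% at P5.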

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

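The tests of list length and of the widest peaks against the whole replicate list were chosen only after the result was seen. Between the first and last stage, 5 of 24 measures moved in opposite directions in every list of the populations, where chance alone gives about 1.33, and the difference between the populations was not tested for any of them. The median peak width rose by 52.5 bp in deep-layer neurons and fell by 164 bp in upper-layer neurons. The share of open regions found in no other list fell by 5.29 percentage points in deep-layer neurons and rose by 27.3 in upper-layer neurons. The share of peaks on chromosome 12 rose by 0.222 percentage points in deep-layer and fell by 0.156 in upper-layer neurons, that on chromosome 17 fell by 0.238 and rose by 0.302, and that on chromosome 18 rose by 0.351 and fell by 0.484. Groups of 2 lists were not tested for outlying lists.

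Lower agreement of the P1 and P5 lists, with each other and with the prenatal lists, accompanies their narrower peaks and their many regions of their own. Shorter lists were examined as a cause. With every list held to the same summed length by its widest peaks, P1 and P5 replicates had Jaccard indices of 0.276 and 0.266, against at least 0.512 for prenatal replicates. With random peaks the values were 0.265 and 0.227 against at least 0.262. With prenatal lists, P1 and P5 lists averaged 0.196 by widest and 0.146 by random peaks. The lowest prenatal pair of different groups had 0.277 and 0.167. Single pairs of a postnatal and a prenatal list reached 0.283 and 0.247. Random thinning drops different peaks from each list, which by itself lowers the index of long lists, so it cannot decide. Deep-layer E16.5 replicate 2 (48.0 Mb) and E18.5 replicate 1 (52.1 Mb) were as short in full as the postnatal lists (45.3 to 52.6 Mb). Their index was 0.453 with each other and 0.154 to 0.276 with postnatal lists. For these lists, compared after the data had been seen, this argues against shorter lists as the whole cause. Of the widest 20000 peaks of the shorter list of each pair, at most 89.2% lay in the whole replicate list for P1 and P5. For the prenatal pairs it was at least 98.95%. The same rank need not be the same strength: median peak widths were 302 to 326 bp in P1 and P5 lists and 390 to 489 bp in prenatal lists. The widths of the 20000 peaks were not matched, so these shares cannot decide on weak peaks as the whole cause. Among the widest 20000 peaks of both lists, the shared part was 64.95% for P1 and 58.3% for P5, and 66.07% for the lowest prenatal pair. Weak peaks therefore stay open as a cause. A change of the neurons after birth and the preparation of these lists cannot be told apart, because all 4 postnatal lists are upper-layer lists and no deep-layer list was made after birth.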

How the results depend on the processing

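Alternatives based on peak width, thinning, coverage of the region, prenatal lists and overlap backgrounds were chosen after seeing the data. Of 292 alternative values, 234 kept their direction and their side of the threshold or stayed within 1.5 times the count. Some of these could not change, such as upper-layer stage counts when a deep-layer list was left out. Stage counts were judged by size alone, although the p of some crossed 0.05, as given below. The 234 therefore overstate how stable the results were. Alternatives by score, and those on genes, promoters and motifs, were not run. Asking for 0.5 of the region or peak to be covered changes nothing by construction, since every peak lies wholly in its region. With an equal number of the widest peaks, 2130 regions passed as open more often in deep-layer and 86 in upper-layer neurons, deep-layer lost regions were 18498 (16944 gained), upper-layer lost regions 43063, lost in both 7047, and open at upper-layer E17.5 only 10651. With the widest 0.5 of each list these were 1297, 107, 16767, 31581, 6315 and 8584, with 8379 gained in deep-layer, 7763 in upper-layer and 433 in both. With random thinning, completely separated regions were 937 and 38, lost regions 14803, 32306 and 3110, and open at E17.5 only 9320. Fewer peaks entered each of these. With 0.5 of the region itself covered, separated regions were 1019 and 62, upper-layer gained 9383, gained in both 348, and open in all deep-layer lists but not at E17.5 1193; the cause was not tested. Autosomes only let 1668 deep-layer and 112 upper-layer regions pass, where the main adjusted p was 0.0501. Age-overlapping stages gave 6538 and 747 separated regions, from fewer lists. The difference in peaks reversed to 0.527 Mb for summed length, and neither passed its test.

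Leaving out each list in turn, 0 regions passed in either direction. Separated regions ranged from 1765 to 2647 and from 123 to 209, deep-layer gained from 13979 to 37580 and lost from 28154 to 64235, upper-layer gained from 14822 to 88565 and lost from 66156 to 110079. The p of the upper-layer lost count was above 0.05 without 5 of the 6 upper-layer lists and that of the deep-layer one without 4 of the 6 deep-layer lists (exact permutation). Gained in both ranged from 702 to 2828, lost in both from 11951 to 19674, open at E17.5 only from 16218 to 43578 and closed at E17.5 only from 2446 to 3932. The gained share differed by 29.6 to 49.2 points in upper-layer and 3.35 to 13.8 in deep-layer lists, and the former missed its threshold without either P1 list (p = 0.0667, exact permutation, the smallest possible there). The latter missed it without any 1 deep-layer list but E18.5 replicate 2 (p = 0.0667 to 0.267, exact permutation). The within-population excess ranged from 0.0270 to 0.108 and the replicate excess from 0.0784 to 0.173. With the replicate block, permuting within replicate number, the within-population difference of 0.0576 had p = 0.01 (200 assignments, exact permutation), and 0 regions passed in either direction (smallest adjusted p 0.106). The block also counts parted replicates as between populations, so its p for the Jaccard index has the same limit as the main one. Same-numbered replicates did not deviate together (correlations -0.114 to 0.0415 over 10 pairs of groups), so the numbers do not pair the lists, and the block changed no call.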

Other observations

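Tests over windows and chromosomes, the comparison with the nearest deep-layer stage, the P1 test within width bins, the count over all splits and the splits for completely separated regions were chosen only after the result was seen. Of 2276 windows of 1 Mb with at least 50 regions open in 2 or more lists, 378 held a larger share of the open regions of deep-layer lists and 239 of upper-layer lists (exact permutation test, two-sided, Benjamini-Hochberg adjusted, smallest adjusted p 0.0170). In 185 of the 378 and 150 of the 239, both upper-layer E17.5 lists also lay outside the range of the 6 deep-layer lists, so the others rest on the postnatal lists, and the windows named here are among the former. On chromosome 8 from 122000001 to 123000000, upper-layer lists had 9.37 ± 2.50 open regions per 10000 and deep-layer lists 3.54 ± 0.802 (SD, n = 6 each). The 3 neighbouring windows on chromosome 11, from 117000001 to 120000000, were also higher in upper-layer lists. Deep-layer lists were higher on chromosome 4 from 13000001 to 14000000, with 6.98 ± 0.723 against 3.37 ± 1.57, and on chromosome 2 from 115000001 to 116000000, with 7.79 ± 0.692 against 4.26 ± 2.06 (SD, n = 6 each). Of 100 splits of the lists, the real one included, 1 gave as many windows as the real 617, and the highest of the others gave 0. The drawn splits missed higher ones: over all splits, 4 gave at least 617 windows, the real one included, and the highest other gave 1137. That split set deep-layer E13.5, deep-layer E16.5 replicate 1, deep-layer E18.5 replicate 2 and upper-layer E17.5 against the other lists, which are the 6 lists with the largest summed peak length (60.6 Mb or more, against 52.6 Mb or less), so it follows a structure of the lists that cuts across populations. With unadjusted p under 0.05 the real split gave 1206 windows, 12 splits gave as many, the highest other 1458 and the median split 31. Most splits part replicates, which resemble each other, so these counts cannot exclude chance among stage groups kept whole. The windows are not shown to follow population. Before birth, both upper-layer E17.5 lists lay outside the range of the 6 deep-layer lists in 677 windows, against 286, 110 and 444 for the 3 deep-layer replicate pairs, too few pairs for a test, and up to 497 for pairs of different stages.

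Chromosome shares of the peaks differed between deep-layer and upper-layer lists for 9 of 20 chromosomes (exact permutation, two-sided, adjusted over the 20). Permuted labels mostly part replicates, which resemble each other, so these p-values do not measure population alone. Chromosome 11 held 5.03% ± 0.651 of the peaks of upper-layer lists and 3.81% ± 0.276 of deep-layer lists (SD, n = 6 each, adjusted p = 0.0173, permutation), and chromosome 3 held 6.08% ± 0.837 and 7.44% ± 0.313 (adjusted p = 0.0173, permutation). Much of this lay in the postnatal lists. For chromosome 3, upper-layer E17.5 lists held 7.0% ± 0.0986, P1 lists 5.40% ± 0.783 and P5 lists 5.83% ± 0.397, beside 7.19% ± 0.240 in deep-layer E18.5 lists (SD, n = 2 each). Both E17.5 lists lay outside the range of the deep-layer lists on 3 of the 9 chromosomes, 11 among them. On 6 of the 9, the postnatal lists lay wholly outside the range of the prenatal lists. The shares are not shown to follow population. The 4 postnatal lists lay above all 8 prenatal lists on 4 chromosomes and below them on 6. Regions gained in upper-layer neurons crowded on chromosome 14, where the window from 4000001 to 5000000 held 95 of them among 217 regions, against 13.8 at the genome-wide share. Unplaced Y sequence held 658 and 1154 peaks in the P1 lists, 147 and 96 in the P5 lists and at most 38 in any prenatal list. Other unplaced sequence held 819 to 927 peaks in the P1 and P5 lists and 226 to 620 in the prenatal lists. How uniquely reads map to these sequences or to the chromosome 14 window was not examined.

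Upper-layer E17.5 lists were closest to the earliest deep-layer stage. Their Jaccard index averaged 0.409 with E13.5 and 0.345 with E16.5 and E18.5, and 0.415 against 0.356 with an equal number of the widest peaks. Both differences were the largest of the 15 choices of 2 deep-layer lists (p = 0.0667, exact permutation, the smallest possible, so the design cannot reach 0.05). P1 and P5 lists were closest to E18.5 instead, at 0.204 against 0.166 and 0.218 against 0.171 (p = 0.0667 for each, exact permutation).

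The share of deep-layer gained regions among the changing regions open in upper-layer lists grew because the lost regions fell, from 56.8% at E17.5 to 5.86% at P5, and not because the gained regions rose (27.3%, 12.9% and 19.6%). Regions open in both deep-layer E13.5 and both E18.5 lists fell too, from 91.2% ± 2.15 at E17.5 to 52.3% ± 7.63 at P1 and 53.5% ± 5.94 at P5 (SD, n = 2 each). Peak strength, with width as its stand-in, is argued against as the cause, since within 10 bins of equal peak width the P5 minus E17.5 difference was 40.3 percentage points, close to the 43.0 without bins. Within these bins the P1 lists averaged 47.6%, and both lay between the E17.5 lists (16.9% and 20.3%) and the P5 lists (55.2% and 62.6%). The number of peaks does not order the lists, since E17.5 replicate 2, with 123229 peaks, lay below P5 replicate 1, with 131337. Summed peak length does part them, at 100.4 and 74.7 Mb for E17.5 and 45.3 to 52.6 Mb for P1 and P5. With an equal number of peaks per list the difference was 46.1 points by widest peaks and 37.2 after random thinning (p = 0.0222 each, exact permutation). The number of peaks is therefore argued against as the cause. These settings did not hold summed length equal, so summed length stays open as a cause. The bins read the same ratio, so an order of stages shared by both populations and the preparation of the postnatal lists cannot be told apart, because no deep-layer list was made after birth.

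The second upper-layer E17.5 list lay almost wholly inside the first. List length is argued against: with an equal number of the widest peaks, 83.8% of one list lay in the other, against at most 76.6% in the deep-layer pairs. Of the narrowest 25% of the peaks of the shorter list, 78.7% lay in the longer list, against at most 52.0% in the deep-layer pairs, which is below the 90% set for 1 library listed at 2 depths and above the 75% set against it. One library listed at 2 depths and a closer pair of samples therefore cannot be told apart, because the value fell between these bounds. No biological explanation was tested.

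For the regions open in all 6 lists of 1 population and in none of the other, 1 of 100 drawn splits, the real one, gave as many as 1849 regions, and the highest of the other drawn splits gave 169. Most splits part replicates, which resemble each other, and this lowers their counts. The splits therefore cannot exclude chance among stage groups kept whole. Among all splits, 1 gave more, 2074 regions. It set deep-layer E13.5, deep-layer E16.5 replicate 1, deep-layer E18.5 replicate 2 and upper-layer E17.5 against the other lists, and so divided them by summed peak length, at 60.6 Mb or more and 52.6 Mb or less, and not by population. The median split gave 4 regions.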
